A study of Homo sapiens with 4 samples.

How the data were processed

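Total RNA from cells labelled HepG2, an established human liver cancer line that the labels class as hepatocellular carcinoma, was sequenced in 4 libraries. Per the labels, 2 libraries came from wild-type cells and 2 from cells resistant to oxaliplatin, a platinum compound that binds DNA. The labels give 2 µg of total RNA per library and paired-end Illumina sequencing with 150-base reads. No step that enriches or depletes an RNA class is described in the sources used here, and whether the kit marks the strand is not given there either. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

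The authors deposited 1 table of estimated counts per transcript, written as whole numbers, with 1 column per library and 106179 transcripts. The unit was read from the values: the columns held only whole numbers, and their totals differed between libraries. Within the wild-type pair, 560 transcripts had a count of 0 in one library and over 1000 in the other, while 51 genes did when the transcripts of each gene were summed. Within the resistant pair the numbers were 670 transcripts and 38 genes. The counts were therefore treated as estimates that share reads among overlapping transcripts. The aligner, the counting tool and the annotation release are not given in the sources used here. The submitters' processing notes list the genome build mm9, a mouse assembly, whereas 103347 of the transcripts carried human Ensembl identifiers and the other 2832 carried identifiers of assembled transcripts. The human identifiers argue against mm9 as the build used for these counts. Which human build was used stays open.

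Transcript identifiers were matched to GENCODE release 29 on GRCh38, which gave a gene, a class and a position for 84072 of the 103347 Ensembl transcripts. The other 19275 Ensembl identifiers and the assembled transcripts had no name in this reference and were described by identifier only. Of the 25806 lincRNA and antisense transcripts of release 29, 25762 were in the table. Of its 83101 protein-coding transcripts, 123 were, so the table holds noncoding transcripts, including those of protein-coding genes, and almost no mRNAs. Coordinates are from release 29 on GRCh38, counted from 1. Older names in the gene lists were matched through the synonyms of the RefSeq table, never to a protein-coding gene. UFC1 in the liver cancer list is a lncRNA that shares its symbol with a protein-coding gene and was left out after seeing the data. List names that the reference did not hold, or whose gene had no transcript in the deposited table, are not analysed here. Of the 20 names of hepatocyte mRNAs, 14 had a gene in the table.

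The deposited counts per library came to 38113398 and 34898860 in wild type and 43473826 and 44063444 in resistant cells. A count of 0 in a library allows up to 3 counts. On the scale of the transcript test this corresponds to 0.0660 to 0.0908 CPM, the usual count scaled to library size, and on that of the gene test to 0.0798 to 0.110 CPM. Such limits cover counting error only. CPM values of transcripts are relative to the counts of the tested transcripts and CPM values of genes to those of the tested genes, both after scaling by trimmed mean of M-values (TMM), so the scales differ. Shares and detection at 1 CPM use the total of the library. No 2 libraries were alike within sampling noise: chi-square per transcript between pairs lay between 240.3 and 300.1, and all 4 were kept.

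Transcripts were tested with the edgeR quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with TMM factors and edgeR's own expression filter at a minimum count of 10, on the counts as deposited. The filter left 42393 transcripts. The same test was run on counts summed per gene over the named transcripts, which left 13745 genes. A gene sum holds the noncoding transcripts of the table only. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 libraries against 2, the smallest exact p of a permutation test is 0.33, so no such test was used for single values. Gene lists were tested with camera in limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation, and with fry, where at least 3 members were tested. Principal components and correlations used log2(CPM + 0.1). Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

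Tests and the 17 gene lists were fixed before the data were examined, as was the rule for named genes. The rule takes, in each direction, up to 12 features past the threshold. Where fewer pass, it adds those of smallest p with a gene name, a mean at or above the median of the tested features and no overlap between the groups, as values that did not pass. It adds the 5 features of highest mean and, from each list, the members that pass or otherwise the 2 of highest mean. Unnamed features are described by their number and at most 2 identifiers per direction. The rule was applied to transcripts and to gene sums, and not every feature it names is reported here.

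The alternatives were no expression filter, a filter at 1 CPM in at least 2 libraries, median-of-ratios size factors, DESeq2 1.42.0, robust empirical Bayes, the replicate number as a block, a minimum change of 2-fold, and leaving out each library in turn. DESeq2 gave no adjusted p for 7372 of 56969 transcripts and 3687 of 17907 genes, which were left out of its counts. limma-voom, the gene-level runs of DESeq2 and robust empirical Bayes, a run without the most abundant assembled transcript and runs with thinned counts, also without each library in turn, were added after seeing the data. The test was also run on the 2 crossed splits, each of which puts 1 library of each group on either side.

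The procedure was tested on simulated data made from the real means and library sizes, with 200 changed features at 2-, 4-, 8- and 16-fold. At the spread estimated from these libraries, edgeR called 0% of the 50 transcripts and 0% of the 50 genes changed 16-fold. DESeq2 called 34% of those transcripts and 96% of those genes, and also 719 unchanged transcripts and 175 unchanged genes. At a dispersion of 0.02, edgeR called 100% of the transcripts and 100% of the genes changed 16-fold.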

Results

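The study compared wild-type cells labelled HepG2, a human liver cancer line, with cells labelled as resistant to oxaliplatin. It asked which long intergenic noncoding RNAs (lincRNAs) differ. RNA-seq gave estimated counts for 106179 transcripts in 2 wild-type and 2 resistant libraries. Wild-type replicates 1 and 2 held 38113398 and 34898860 counts, and resistant replicates 1 and 2 held 43473826 and 44063444. Counts above 0 were found for 45460 and 44612 transcripts in wild type and for 47555 and 47541 in resistant cells. Noncoding transcripts of protein-coding genes, such as retained introns, took 70.0% ± 0.490 of the counts in wild type and 73.6% ± 0.646 in resistant cells (SD, n = 2 libraries each). lincRNA genes took 3.33% ± 0.335 and 3.45% ± 0.0745.

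Summed over the transcripts of each gene, the smallest p-values for a higher mean in resistant cells belonged to noncoding transcripts of *EEF1A1*, the translation elongation factor, and of *NKAIN3*, which encodes a partner of the sodium pump. *EEF1A1* (ENSG00000156508) was at 50.2 ± 0.197 CPM in wild type and 2345 ± 203 CPM in resistant cells (SD, n = 2), a 46.7-fold higher mean. *NKAIN3* (ENSG00000185942) had no count in either wild-type library and 8137 and 6300 counts in the resistant ones, at least 1837-fold higher against a limit of 3 counts per library. This bound covers counting error only, and the sum holds no mRNAs. A single transcript held 98.9% of the *EEF1A1* counts and 100% of the *NKAIN3* counts in resistant cells. For these genes the sum therefore adds little to the single transcript and cannot exclude sharing of reads with mRNAs. Within the wild-type pair 51 gene sums, and within the resistant pair 38, were at 0 in 1 library and over 1000 in the other. In the other direction, *POU2F1*, the gene of the transcription factor OCT1, had a mean of 2137 ± 126 CPM in wild type and 207 ± 15.8 CPM in resistant cells, 10.3-fold lower. *PTPRS*, a receptor tyrosine phosphatase gene, had 1318 ± 251 and 91.4 ± 14.6 CPM, 14.4-fold lower. None of these differences passed adjustment for the number of genes tested in edgeR, the main test. All passed in DESeq2, whose calls on simulated data included 175 unchanged genes. DESeq2 also called genes on the crossed splits of these libraries, as given below.

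Across all 13745 genes, the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes (smallest adjusted p = 0.323). At an unadjusted p under 0.05 it gave 1192 genes, 652 with a higher and 540 with a lower mean in resistant cells. limma-voom called 0 and DESeq2 called 714, of which 395 were higher and 319 lower. On the crossed splits, with 1 library of each group on either side, DESeq2 called 350 and 390 genes. The estimated common dispersion was 0.542, a coefficient of variation between libraries of 0.736. On counts simulated with the dispersion estimated for each gene, the edgeR test called no gene changed 16-fold. A count of 0 therefore does not exclude changes of that size.

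The 12 genes of smallest p with a higher mean in resistant cells are given as values that did not pass (edgeR adjusted p = 0.323 for each). For 8 of them, both wild-type libraries had a count of 0. They include *SNTB2*, a syntrophin gene, at 55.1 ± 7.61 CPM in resistant cells, at least 521-fold higher. *UBXN2B* was at 26.0 ± 0.599 CPM and *NIPAL1*, a magnesium transporter gene, at 40.0 ± 9.12 CPM, at least 245-fold and 378-fold higher. These bounds cover counting error only. Noncoding transcripts of *SRSF4*, a splicing factor gene, had 23.4 ± 2.44 CPM in wild type and 185.1 ± 33.3 CPM in resistant cells, 7.92-fold higher. Those of *EZH2*, the histone H3 lysine methyltransferase of Polycomb, had 0.871 ± 0.275 and 20.5 ± 2.06 CPM, 23.6-fold higher (SD, n = 2 throughout).

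Among the 12 genes of smallest p with a lower mean in resistant cells, the noncoding transcripts of *XRCC3*, a homologous recombination gene, had 93.1 ± 3.81 CPM in wild type and 18.7 ± 1.46 CPM in resistant cells, 4.98-fold lower (SD, n = 2). *HSD17B4*, a gene of peroxisomal fatty acid oxidation, had 901.7 ± 53.3 and 196.0 ± 22.0 CPM, 4.60-fold lower. *MINK1*, a kinase gene, had 431 ± 2.79 and 50.9 ± 0.289 CPM, and *MRM2*, a methyltransferase gene of mitochondrial rRNA, had 130.1 ± 8.03 and 9.61 ± 1.10 CPM. *ALDH1A3*, which encodes a retinaldehyde dehydrogenase, had 24.3 ± 2.32 and 1.97 ± 0.190 CPM, 12.3-fold lower. *DBNL*, *RABL3* and *CBWD6* had means 5.03-, 13.6- and 5.69-fold lower in resistant cells. *ZNF695*, with 2388 and 1284 counts in wild type and 0 in both resistant libraries, was at least 790.5-fold lower. That bound covers counting error only. *EEF1A1* has many processed pseudogenes and *CBWD6* has near-identical copies, so how their reads were shared is uncertain.

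**Figure D1:**
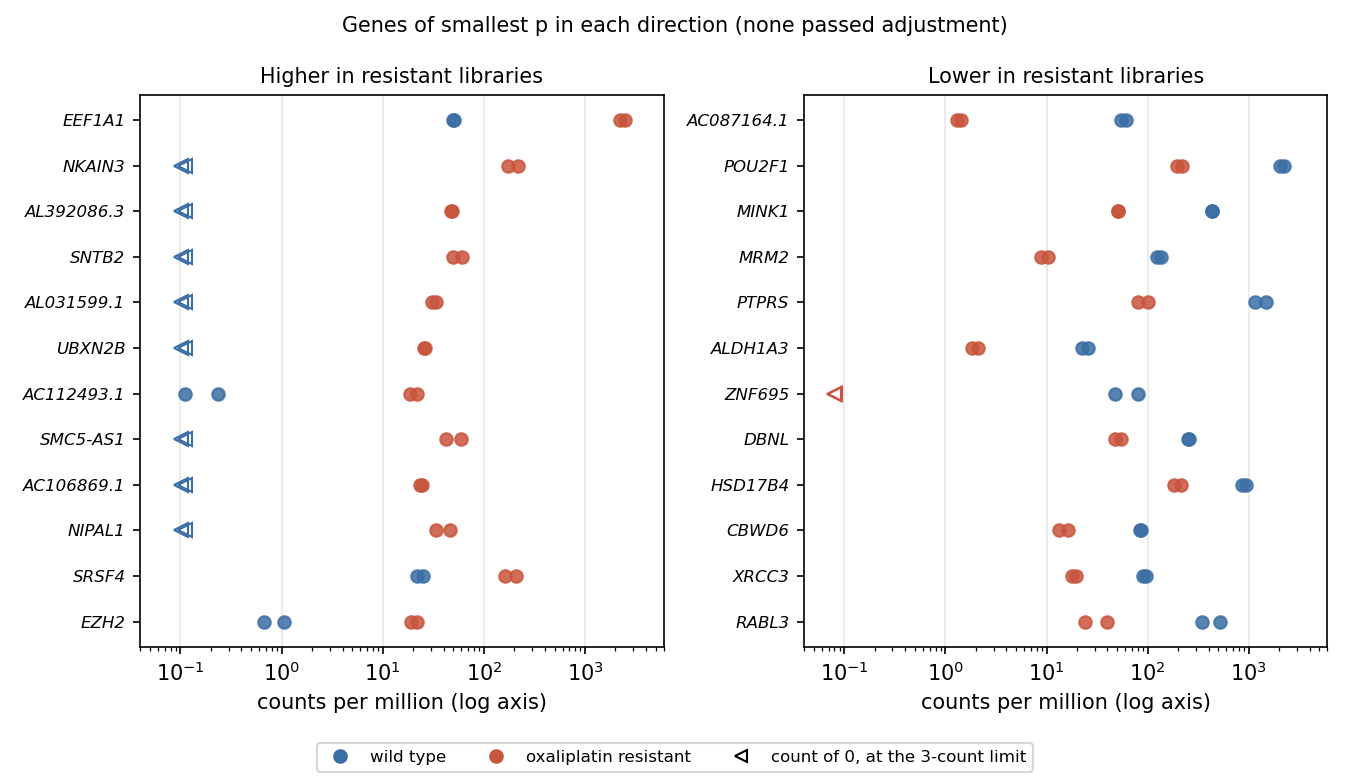
Gene-level CPM (log axis, relative to the counts of the tested genes after TMM scaling) of the 12 genes of smallest p in each direction, with 1 point per library. Open triangles mark counts of 0, drawn at the limit of 3 counts. The 2 libraries of each group do not overlap with those of the other for any gene shown, and none passed adjustment (edgeR adjusted p = 0.323).

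The lincRNA genes, the class the study asked about, included 4 of the 12 genes with a higher mean. *AL392086.3* lies at GRCh38 chromosome 10, 6737418 to 6840712, plus strand, and had 0 counts in wild type against 1826 and 1712 in resistant cells, at least 451-fold higher. *AL031599.1*, at chromosome 1, 172775905 to 173064015, plus strand, had 0 against 1259 and 1120 counts, at least 303-fold higher. *AC106869.1*, at chromosome 2, 47192405 to 47345074, minus strand, had 0 against 915 and 845 counts, at least 224-fold higher. *AC112493.1*, at chromosome X, 27042907 to 27176298, minus strand, had 7 and 3 counts in wild type and 828 and 677 in resistant cells. The antisense gene *SMC5-AS1*, at chromosome 9, 70193997 to 70258866, minus strand, had 0 against 1603 and 2165 counts. Another antisense gene, *AC087164.1* at chromosome 17, 18172625 to 18184753, minus strand, had 57.9 ± 4.78 CPM in wild type and 1.36 ± 0.0828 CPM in resistant cells, 42.5-fold lower. Reads of an antisense gene cannot be told apart from those of the gene it overlaps, since the use of strand is not given. These sums cover named transcripts only, so reads of the same gene may lie on Ensembl identifiers without a name. The fold bounds cover counting error only. Of 1369 lincRNA genes tested, 135 had an unadjusted p under 0.05 in edgeR, 84 higher and 51 lower in resistant cells. The crossed splits gave 73 and 85 lincRNA genes.

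At the level of single transcripts, several genes had a transcript counted in 1 group and at 0 in the other while the gene sum differed far less. *LINC00511*, a long noncoding gene on chromosome 17, appears in both directions. Its transcript ENST00000650131, with 4 exons at GRCh38 72403322 to 72592804, minus strand, had 12708 and 11254 counts in wild type and 0 in both resistant libraries. ENST00000648623, with 5 exons at 72403322 to 72592692, had 0 counts in wild type and 21180 and 30773 in resistant cells. The sum over *LINC00511* was 19300 and 14386 counts in wild type and 32067 and 42539 in resistant cells, a log2 fold change of 0.77 ± 0.29 (SE; edgeR adjusted p = 0.610). For *CDKN2B-AS1*, the antisense RNA of the *CDKN2B* locus, ENST00000582072 had 1556 and 1685 counts in wild type and 0 in resistant cells. The sum over *CDKN2B-AS1* was 9939 and 7127 against 9916 and 10183.

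The test of 42393 transcripts gave 0 calls (edgeR, smallest adjusted p = 0.329). It gave 3283 transcripts at an unadjusted p under 0.05, of which 1935 were higher and 1348 lower in resistant cells. limma-voom called 0 and DESeq2 called 3235, 1909 higher and 1326 lower. On the crossed splits DESeq2 called 2451 and 2406 transcripts. The common dispersion was 0.941. Transcripts changed 16-fold, simulated with the dispersion estimated for each transcript, were not called by edgeR either. In 17087 transcripts, or 40.3%, the groups did not overlap, where chance gives 33.3% for 2 libraries against 2.

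Of the 12 transcripts of smallest p with a higher mean in resistant cells, 11 belong to protein-coding genes (edgeR adjusted p = 0.329 for each). ENST00000490569, a retained-intron transcript of *EEF1A1* at chromosome 6, 73517519 to 73520059, minus strand, had 726 and 583 counts in wild type and 81739 and 90189 in resistant cells. It made up 45.9% of the gene's counts in wild type and 98.9% in resistant cells. ENST00000571669 of *METTL16*, an RNA methyltransferase gene, had 0 against 9513 and 7370 counts, and the sum over *METTL16* was 1040 and 1607 against 11130 and 9323. A retained-intron transcript of *RNF213*, ENST00000559070, had 59.1 ± 3.64 and 600.0 ± 12.5 CPM (SD, n = 2), and the gene had a log2 fold change of 1.85. Transcripts of *CCT6A* (ENST00000462133) and *CNOT3* (ENST00000618939) had means 116.8- and 144.6-fold higher, while their gene sums had log2 fold changes of 1.32 and 2.58. The *CNOT3* transcript had 2 and 3 counts in wild type, within the limit of 3 counts, so its fold is uncertain. ENST00000485515 of *SDHB*, a succinate dehydrogenase gene, had 0 against 9098 and 9675 counts, with a gene-level log2 fold change of 0.67. For *MEAF6* (ENST00000487788), *PCSK7* (ENST00000528973) and *ZCCHC7* (ENST00000461038), gene-level log2 fold changes were -0.26, 0.21 and 0.81.

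Of the 12 transcripts of smallest p with a lower mean in resistant cells, 10 belong to protein-coding genes (edgeR adjusted p = 0.329 for each). ENST00000491632, a retained-intron transcript of *ARID4B* at chromosome 1, 235177616 to 235328168, minus strand, had 918.1 ± 143.3 CPM in wild type and 11.6 ± 2.43 CPM in resistant cells (SD, n = 2), 79.1-fold lower. The sum over *ARID4B* had a log2 fold change of -1.98. ENST00000476803 of *FAAP20*, a gene of the Fanconi anaemia core complex, had 1135 and 1061 counts in wild type and 13 and 7 in resistant cells, and the gene sum had a log2 fold change of -4.67. ENST00000497594 of *PPARG*, a nuclear receptor gene, was 31.2-fold lower, whereas the sum over *PPARG* was 3899 and 3073 counts in wild type and 5306 and 11904 in resistant cells. *PTPRS* (ENST00000588552) and *MINK1* (ENST00000572330) had transcripts 14.7-fold and 9.72-fold lower, which held 97.2% and 85.4% of their gene's counts in resistant cells. Transcripts of *OXA1L* (ENST00000495424), *FBXO34* (ENST00000555087), *PPP2R5C* (ENST00000556068) and *SELENBP1* (ENST00000498494) had 0 counts in both resistant libraries, while their gene-level log2 fold changes were -0.49, 0.28, -0.11 and -1.29. A transcript of *ATL2* (ENST00000472097) was 14.2-fold lower, with a gene-level log2 fold change of -1.19.

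**Figure D2:**
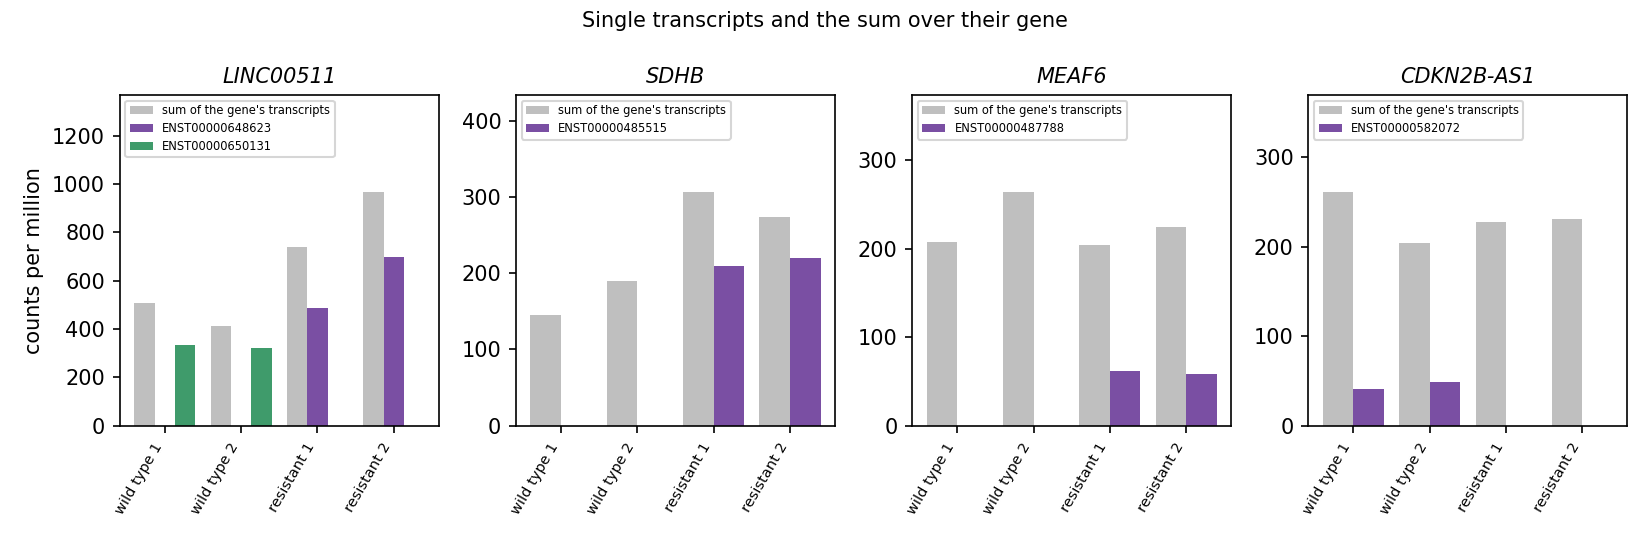
CPM relative to all counts in the library for 5 transcripts (coloured bars) and for the sum over the transcripts of their gene (grey bars) in each of the 4 libraries. The transcripts of *LINC00511*, *SDHB*, *MEAF6* and *CDKN2B-AS1* shown were at 0 in both libraries of 1 group, whereas every gene sum was above 0 in all 4 libraries.

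Of the unnamed transcripts, 329 of 2919 tested Ensembl identifiers outside release 29 and 197 of 2076 assembled transcripts had an unadjusted p under 0.05 in edgeR. The crossed splits gave 239 and 275 of the former and 104 and 101 of the latter. ENST00000664983 had 7591 ± 38.4 CPM in wild type and 38.1 ± 10.2 CPM in resistant cells, and ENST00000660405 had 0 and 246.0 ± 64.3 CPM (SD, n = 2). Neither passed adjustment in edgeR (adjusted p = 0.329 for both).

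The most abundant feature was the assembled transcript TCONS_00347441, which took 5.81% and 5.52% of the counts in wild type and 2.67% and 2.94% in resistant cells. Its log2 fold change was -1.12 ± 0.20 (SE; edgeR adjusted p = 0.338). The next were TCONS_00341423, at 10974 ± 1938 and 9058 ± 1123 CPM, a transcript of the glycolytic gene *ENO1* (ENST00000464920), at 9144 ± 733 and 8040 ± 310 CPM, TCONS_00025993, at 9440 ± 267 and 5857 ± 1309 CPM, and a transcript of the glycolytic gene *GAPDH* (ENST00000474249), at 6839 ± 2123 and 7140 ± 782 CPM (SD, n = 2, wild type first). Among gene sums, *ENO1*, *TRIO*, *GAPDH*, *CYTOR* and *MIR4435-2HG* had the highest means. *TRIO* had 14431 ± 112 CPM in wild type and 15014 ± 5970 CPM in resistant cells. *CYTOR* and *MIR4435-2HG* are near-identical lncRNA genes whose reads cannot be assigned with certainty. *CYTOR* had 8149 ± 440 and 5043 ± 1254 CPM and *MIR4435-2HG* had 5930 ± 1460 and 6993 ± 1621 CPM.

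Among lncRNAs with a known link to liver cancer, platinum response or p53, no member passed the test (edgeR with Benjamini-Hochberg adjustment, over all genes and adjusted over the list alone). The liver cancer list had 30 tested members and the platinum and drug resistance list 18. Of these, *MALAT1*, the abundant nuclear lncRNA, had 3135 ± 615 CPM in wild type and 4512 ± 1350 CPM in resistant cells (SD, n = 2). Of the 16 tested p53 and DNA damage lncRNAs, *PVT1* had 2004 ± 455 and 1665 ± 456 CPM and *LINC-PINT* 650.3 ± 273.0 and 638 ± 253 CPM. *H19* and *SNHG14*, of the imprinted list with 4 tested members, had 260.0 ± 57.5 against 149.2 ± 13.3 CPM and 236 ± 38.4 against 327 ± 24.5 CPM. *GAS5* and *C6orf48*, of the 29 tested hosts of snoRNAs, had 1656 ± 359 against 1255 ± 48.6 CPM and 1830 ± 177 against 1450 ± 148 CPM. *NEAT1*, in the list of 11 hypoxia and oxidative stress lncRNAs, had 513 and 19123 counts in wild type and 831 and 359 in resistant cells. Its log2 fold change of -4.49 came to -0.12 without wild-type replicate 2.

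The 17 tested EMT and invasion lncRNAs were led by *CYTOR* and *MIR4435-2HG*, whose values are given above. Of the 19 tested HOX cluster lncRNAs, *HOTAIRM1* had 55.3 ± 12.1 CPM in wild type and 78.5 ± 10.4 CPM in resistant cells, and *HOXC13-AS* had 10.4 ± 0.683 and 18.1 ± 6.47 CPM (SD, n = 2). *NORAD*, of the 5 tested abundant nuclear and structural RNAs, had 430.0 ± 2.68 and 497 ± 63.2 CPM. Among noncoding transcripts of genes of platinum transport, glutathione and efflux, *ABCC3* had 427 ± 6.71 and 255 ± 30.6 CPM, and *ABCC4* 232 ± 33.2 and 223 ± 23.6 CPM. Both encode efflux pumps, and 0 of the 16 tested members passed. Among those of DNA repair genes, *DDB2* had 208 ± 22.3 and 247 ± 40.6 CPM and *ERCC3* 190.9 ± 4.94 and 170.3 ± 68.5 CPM, with 0 of 17 passing. *TNFRSF10B*, a death receptor gene among 15 tested p53 targets, had 865 ± 362 and 633 ± 74.0 CPM, and 0 members passed.

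No list as a whole passed camera at a preset correlation of 0.01, with 14 lists tested. Adjusted p was 0.614 for the liver cancer, platinum, snoRNA host, imprinted, hypoxia and fibroblast and endothelial lists. It was 0.824 for the p53 lncRNA and EMT lists and 0.986 for the HOX list. For the hepatocyte lncRNA, nuclear RNA, transport, DNA repair and p53 target lists it was 0.875. With an estimated correlation, adjusted p was 0.896 or 0.990 for each of the 14. fry, which tests a list by itself, gave no adjusted p under 0.05 for a change in 1 direction with all libraries (lowest 0.184, the p53 lncRNA list, which came to 0.0495 without wild-type replicate 2). For change in either direction it gave 0.0167 for the fibroblast and endothelial list. The value was 0.0454 with the replicate number as a block and 0.0658 to 0.224 in the 4 leave-one-out runs of fry, where 1 group is a single library and the other alone gives the spread (adjusted p from limma). That list holds *LINC00968*, with 1 and 0 counts in wild type and 643 and 522 in resistant cells, the only member of any list past the threshold when adjusted over the list alone (adjusted p = 0.00639, edgeR). *LINC00968* did not pass over all genes in edgeR (adjusted p = 0.323), and was named because of that count. In the snoRNA host, EMT, nuclear RNA, DNA repair and transport lists, the median, the mean and the direction of camera differed in sign.

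Hepatocyte genes were near 0 in wild-type and resistant cells alike. Of 24 hepatocyte-enriched lncRNAs in the table, 19 had a count of 0 in all 4 libraries, among them *LINC01018*, *LINC00261*, *HNF4A-AS1* and *FAM99A*. *LINC00907* had 8.93 ± 8.62 CPM in wild type and 5.45 ± 2.07 CPM in resistant cells, and *CPS1-IT1* had 7.21 ± 1.99 and 6.21 ± 0.169 CPM (SD, n = 2). Noncoding transcripts of 14 hepatocyte genes were in the table, and 11 of these genes, *AFP*, *TTR* and *SERPINA1* among them, had a count of 0 in all 4 libraries. Those of *ALB* had 8 counts in wild-type replicate 1 and 0 elsewhere, and those of *FGG* had 3 and 9 counts in wild type and 8 and 74 in resistant cells. Of the DNA repair and p53 target genes, 27 of 31 reached a mean of 1 CPM over the 4 libraries, against 0 of the 14 hepatocyte genes (two-sided Fisher's exact test over genes, p = 1.8e-08). Genes are not independent replicates, and mRNAs are not measured here, so the values speak only of the noncoding transcripts listed.

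Blood cell and pluripotent or neural markers were sparse as well, whereas some fibroblast and endothelial lncRNAs were counted. Of the blood cell lncRNAs, 1 of 11 reached a mean of 1 CPM, *ITGB2-AS1* with 1.09 ± 0.437 CPM in wild type and 1.39 ± 0.184 CPM in resistant cells (SD, n = 2). *LINC00926* had 0.457 ± 0.0231 and 0.231 ± 0.214 CPM. Of the pluripotent or neural lncRNAs, 1 of 13 did, *SOX2-OT*, with 420 and 594 counts in wild type and 0 and 414 in resistant cells. *LINC00678* had 19 counts in resistant replicate 1 and 0 elsewhere. Of the fibroblast and endothelial lncRNAs, 4 of 12 did, led by *MIR100HG* with 150.4 ± 4.87 and 94.0 ± 31.8 CPM and *FENDRR* with 6.61 ± 3.28 and 21.3 ± 12.2 CPM.

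**Figure D3:**
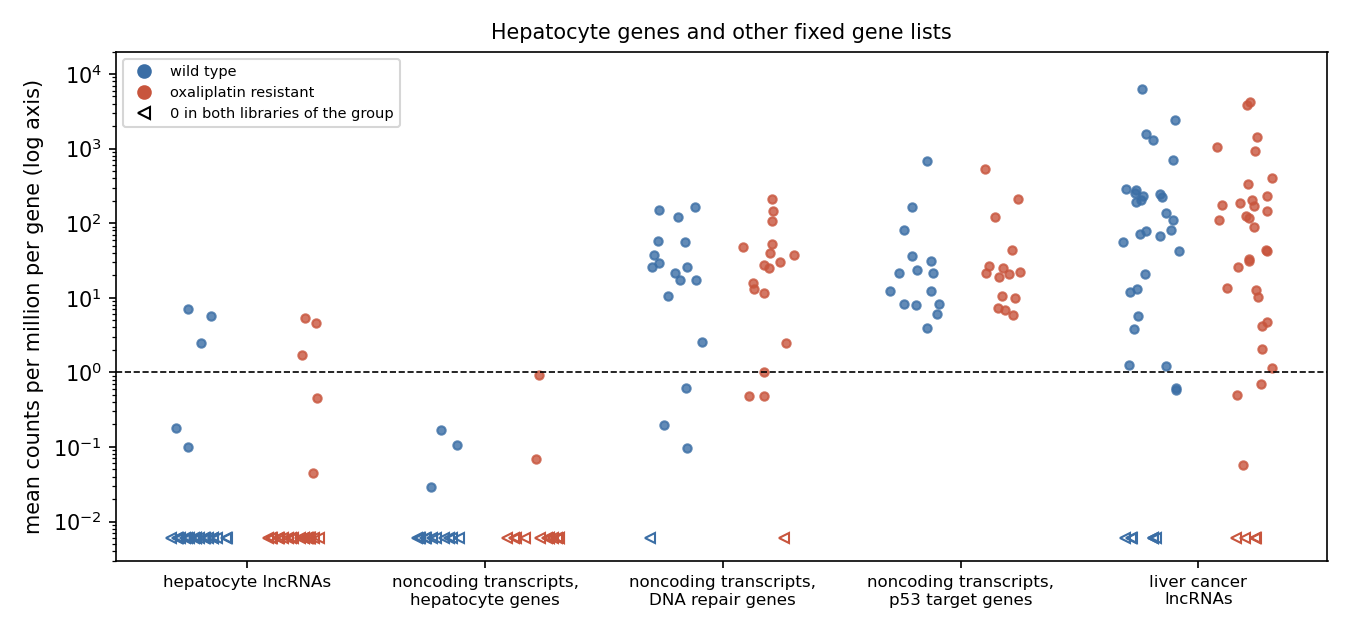
Mean CPM per gene (log axis, relative to all counts in the library) in wild-type and resistant cells for 5 gene lists, with 1 point per gene and group. Open triangles at the bottom mark genes with a count of 0 in both libraries of the group, and the dashed line marks 1 CPM. Of 14 hepatocyte genes, 0 reached a mean of 1 CPM over the 4 libraries, against 27 of 31 DNA repair and p53 target genes.

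Transcripts listed in a single group were more frequent in resistant cells, by a smaller ratio when a wild-type library was left out. Above 0.1 CPM of the library total in both libraries of a group, and at 0 in both of the other, were 1293 transcripts in resistant and 592 in wild-type cells, a ratio of 2.18. The ratio was 1.53 without wild-type replicate 1 and 1.26 without wild-type replicate 2 (2699 against 2150), and 2.22 and 2.20 without resistant replicates 1 and 2. With a library left out, 1 library stands for a group, so the condition differs and these ratios are not directly comparable with 2.18. The named examples above include transcripts of *SDHB*, *METTL16* and *ZCCHC7* in resistant cells and of *OXA1L* and *SELENBP1* in wild type. The same count for the crossed splits was 1383 and 1359 transcripts in all, against 1885 for the real split. For gene sums, 358 genes such as *NKAIN3* and *SNTB2* were listed only in resistant cells and 124, such as *ZNF695*, only in wild type, with 329 and 330 genes in all for the crossed splits. Without wild-type replicate 2 these came to 682 and 519 genes. Across 42393 transcripts, the Pearson correlation of log2(CPM + 0.1) was 0.678 between the wild-type libraries and 0.717 between the resistant ones, against 0.656 to 0.674 between groups. Transcripts are not independent replicates. The Spearman correlation was 0.692 and 0.739 within groups and 0.678 to 0.696 between them. The first principal component, with 38.3% of the variance, separated the groups. The other components held 33.9% and 27.7%, so the first was not dominant.

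**Figure D4:**
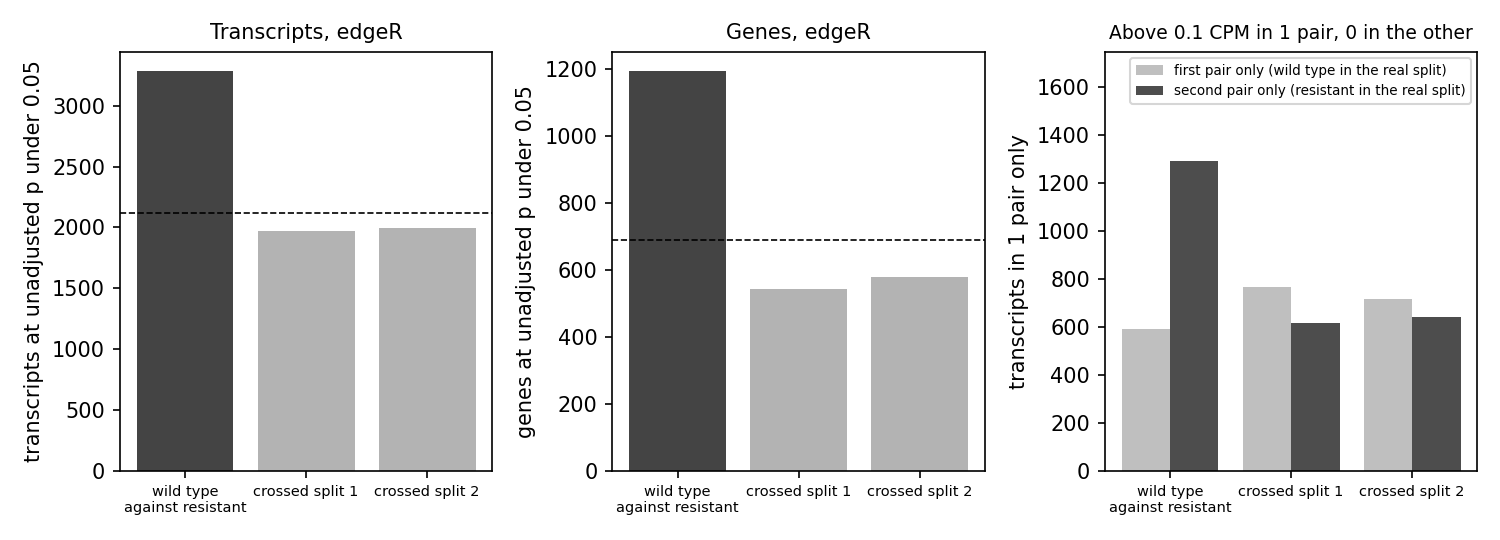
Number of transcripts (left) and genes (middle) at an unadjusted p under 0.05 in edgeR for the real split of the 4 libraries and for the 2 crossed splits, with a dashed line at 5% of the tested features. The right panel gives the transcripts above 0.1 CPM in both libraries of 1 pair and at 0 in the other pair. The real split gave 3283 transcripts and 1192 genes, and 1293 transcripts only in resistant against 592 only in wild-type libraries.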

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

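limma-voom, the gene-level runs of DESeq2 and robust empirical Bayes, the run without the most abundant assembled transcript and the thinned counts, also without each library, were chosen after seeing the data. The number of edgeR calls was 0 for transcripts and genes in the main test and in every edgeR or limma-voom alternative, leave-one-out runs included. These zeros show no stability, since edgeR called no feature in simulated data of this spread with all libraries, and without a library the other group alone gives the spread. DESeq2 called 3235 transcripts and 714 genes, with 5872 transcripts and 1849 genes at an unadjusted p under 0.05, and the cause was not tested. On the crossed splits DESeq2 called 2451 and 2406 transcripts and 350 and 390 genes. All 24 named transcripts and all 24 named genes passed the threshold in DESeq2, but they were picked for small p and no overlap in the same libraries, which also fixes their direction in other runs. With the replicate number as a block, 1961 transcripts and 781 genes had an unadjusted p under 0.05, and the calls stayed at 0. Libraries of the same number did not deviate together (correlation 0.0083 for transcripts and -0.019 for genes), but with 2 pairs a weak shared effect could be missed. With fry for change in either direction, 1 list passed (0 with camera), which tests another hypothesis, and its adjusted p was 0.0454 with the replicate block and 0.0658 to 0.224 in leave-one-out runs. In 1 direction, the p53 lncRNA list passed only without wild-type replicate 2 (0.0495, and 0.184 with all). Of the values of named list members, 14 differed from the main value by more than its SE, 12 of them in leave-one-out runs. The log2 fold change of *LINC00907* was 0.94 without wild-type replicate 2 (-0.71 with all), and without wild-type replicate 1 those of *LINC-PINT* and *TNFRSF10B* were 0.48 and 0.06 (-0.03 and -0.45 with all). Correlation within minus between groups was 0.0317, 0.0219 with a pseudocount of 1, 0.0410 over transcripts at 1 CPM or above in at least 2 libraries, and 0.0118 to 0.0589 in leave-one-out runs. It was lowest without either resistant library. Transcripts in a single group numbered 1250 above 0.5 CPM and 936 above 1 CPM, where fewer transcripts qualify, and 4849 to 5006 in leave-one-out runs (4966 and 4905 without wild-type replicates 1 and 2 and 5082 and 5058 without resistant replicates 1 and 2 after thinning), where 1 library stands for a group. Other pseudocounts in the test, quantile normalization and limma without trend apply to normalized values and were not run. Depth sets the limit for features near 3 counts per library.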

Other observations

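The tests on hepatocyte genes, on genes with 1 transcript, on thinned counts and on medians per chromosome were chosen after the patterns were seen, as was the comparison of splits by unadjusted p. The bounds of the test on thinned counts with all libraries were set before its result was known. A few genes outside the rule for named genes were picked after their values were seen, and none passed adjustment (edgeR). *ATP7B*, which encodes a copper pump that also handles platinum compounds, had noncoding transcripts at 67.6 ± 2.10 CPM in wild type and 27.5 ± 1.79 CPM in resistant cells (SD, n = 2, adjusted p = 0.383). *PARP1*, the poly(ADP-ribose) polymerase gene, had 73.0 ± 28.7 and 32.9 ± 2.49 CPM (adjusted p = 0.572). *PINCR*, a p53-induced lncRNA, had 39 and 45 counts in wild type and 154 and 234 in resistant cells. *HOXA10-AS* had 38 and 40 counts in wild type and 0 in both resistant libraries. *LRRC75A-AS1*, a snoRNA host, had 1872 ± 97.1 and 998 ± 23.4 CPM (adjusted p = 0.393).

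*LINC01133* and *SPRY4-AS1*, of the EMT and invasion list, had means apart in opposite directions and did not pass (edgeR adjusted p = 0.480 and 0.475): *LINC01133* had 19.9 ± 4.22 CPM in wild type and 43.6 ± 0.173 CPM in resistant cells, and *SPRY4-AS1* had 63.2 ± 20.6 and 24.5 ± 3.47 CPM (SD, n = 2). *S100P*, which encodes a calcium-binding protein, had 17.7 ± 0.456 CPM in wild type and no count in resistant cells. *ERBB3*, a receptor gene of the EGFR family, had noncoding transcripts at 6.03 ± 0.103 and 0.257 ± 0.0620 CPM. *OSMR-AS1* had 18.1 ± 1.71 and 106.8 ± 8.03 CPM (edgeR adjusted p = 0.323 for these 3 genes). Assembled transcripts as a class took 14.0% ± 0.314 of the counts in wild type and 10.5% ± 0.0298 in resistant cells. Without TCONS_00347441 their share was 7.93% and 8.67% in wild type and 7.88% and 7.57% in resistant cells.

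Hepatocyte genes such as *ALB*, *AFP* and *TTR* had almost no counts in libraries labelled as a liver line. Counting that misses noncoding transcripts of all coding genes, or low depth, is argued against by the DNA repair and p53 target genes, of which 27 of 31 reached 1 CPM. Fisher's exact test against the hepatocyte genes (p = 1.8e-08) adds little, since their low counts prompted it. The pattern includes the wild-type cells: 3 of 38 hepatocyte genes of both lists reached a mean of 1 CPM in wild type and 3 in resistant cells. What stays open is that the cultures may have lost liver expression or may be another cell line than labelled, since 0 of the 38 genes reached 10 CPM in wild type. These cannot be told apart without a HepG2 reference. Liver mRNAs may also have been present with few reads on these noncoding transcripts, since mRNAs are not measured here. A filter on the deposited transcripts was not tested.

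More transcripts were listed only in resistant than only in wild-type cells. The deeper resistant libraries could give such an excess, but after thinning every library to the smallest total the ratio of the numbers was 2.14, close to 2.18 before. The ratio was smaller when a wild-type library was left out: without replicate 1 or 2 of wild type it was 1.53 or 1.26, and 1.51 or 1.27 after thinning. A group left with 1 library meets the condition for its own transcripts more easily, which could lower these ratios. The ratio did not rise in the same way without resistant replicate 1 or 2, at 2.22 and 2.20, and at 2.19 and 2.16 after thinning. Among genes with 1 named transcript in the table, 195 were listed only in resistant and 63 only in wild-type cells, a ratio of 3.1. Such genes can have further transcripts among the mRNAs or among the identifiers without a name. The ratio therefore cannot decide whether reads shared out differently among the transcripts of a gene gave the excess. Among these genes the ratio came to 1.53 and 1.23 without wild-type replicates 1 and 2, where 1 library stands for wild type. These lower ratios cannot decide on such sharing either, since the condition differs. A biological difference between resistant and wild-type cells stays open and is untested beyond these ratios, as does exchange of reads with mRNAs, which the table does not hold.

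The 3 splits of 4 libraries into pairs are too few for a share under 0.05. The real split gave 3283 transcripts at an unadjusted p under 0.05 and the highest other 1997, and for genes 1192 and 578, with 1 split reaching the real value in each case. Medians of the log2 fold change per chromosome were small: that of chromosome 5, over 464 genes, was 0.097, against up to 0.127 in size for the crossed splits.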
